A study of Mus musculus with 8 samples.

How the data were processed

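RXR ChIP-seq was performed on hearts of newborn mice, with 4 immunoprecipitated and 4 matching input libraries from 2 WT and 2 edKO hearts. Per the labels' protocols, chromatin of each fixed heart was sheared and immunoprecipitated with an RXR antibody, part of it was kept as input, and each heart was a biological replicate. The tissue was the total heart, while the deletion was limited to cardiomyocytes. The labels name both a paired-end run format and single-end reads, and give only an average read number. Per the submitters' processing notes, reads were processed with cutadapt, BWA, SAMtools and MACS3 on the mouse build mm10 (GRCm38). The versions and settings of these tools are not given in the sources used here. The labels name 1 peak list per heart for its immunoprecipitate and its input, so peaks were called per heart and not on pooled hearts, and the input libraries entered only as background.

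The deposited lists hold 23961 peaks in the narrowPeak layout. The authors' fold enrichment is a ratio of the fragment pileup at a peak's summit to the local background. The authors' −log10 p and −log10 q values give the significance of a peak against that background within its own list, and the smallest deposited −log10 q, 1.37, lay just above the value of 1.30 that a q of 0.05 gives. The deposited positions are the start, end and summit of each peak in bp on mm10, and coordinates are printed 1-based. Because q depends on the list, the −log10 p behind a given q can differ between lists. The smallest −log10 p was 3.85 in WT replicate 3, 4.70 in WT replicate 4, 9.53 in edKO replicate 3 and 6.03 in edKO replicate 4. The smallest −log10 q was 1.37, 1.57, 3.53 and 1.47 in the same order. In edKO replicate 3 the weakest of 8 peaks thus lay well above a q of 0.05 on this scale, and 9.53 does not mark that threshold. Fold enrichment was used to describe and rank peaks within a list, and the mean over the WT hearts ranked shared regions.

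The depth of each library was recovered from the peak statistics. The fold enrichment (with a pseudocount of 1) and the −log10 p of a Poisson upper tail were solved together for the fragments at the summit and the local background. In all 4 lists 100% of the peaks gave a whole number of fragments within 0.02, after scaling of the immunoprecipitate to its input in WT replicate 4 and edKO replicate 3. The local backgrounds above the lowest value of their list and under a fixed upper limit were set against a grid of 0.2 fragments. This is the ratio of a 200 bp extension to a 1000 bp local window. Between 95.5 and 100% of them lay on the grid within 0.01 of a step, at the scale that gave the best fit. In edKO replicate 3 the 100% rests on part of a list of 8 peaks. The lowest number of fragments at a summit was 11 in WT replicate 3, 12 in WT replicate 4, 24 in edKO replicate 3 and 17 in edKO replicate 4. The background is in fragments per position after extension and corresponds to 12.4, 12.0, 15.7 and 14.8 fragments per kb in the same order. Whether duplicate reads had been removed is not given in the sources used here, so intervals cover counting error only.

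Peaks overlapping by at least 1 bp were treated as shared. A peak of WT replicate 4 was joined to its strongest partner in WT replicate 3, with 1 peak per heart in a region, the region covering both peaks and the summit being that of WT replicate 3. Background overlap came from 100 random placements within the annotated span of each chromosome (seed 20). Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the same build as the peaks, with 21887 protein-coding genes used of 49997 entries. The table has no strand, so the distance to either gene end replaced the planned distance to a transcription start, and the share within 1000 bp of a gene end replaced the planned promoter share. No genome sequence was used here, so the planned motif comparison was not run. All 435 entries of the 18 gene lists, which hold 422 genes, matched the table, 1 of them by an older symbol. A gene counted as near a region when the summit lay within 10 kb of either end.

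Lists were compared with all other protein-coding genes by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. Genes and peaks are not replicates, so these tests describe the regions of the WT hearts. Neighbouring genes can share a region, and lists share members. Shares have 95% Clopper-Pearson intervals. Peak numbers were compared by an exact permutation test. The number of a heart is shared between genotypes, but the labels do not say that it marks a litter or a day, so the hearts were treated as unpaired. The lists, tests and alternatives were fixed before the data were examined, except the use of gene ends, a common −log10 p threshold of 10, 5 added gene lists and the tests of a uniform remainder and of carried-over material in the closing observations, which were chosen after seeing the data.

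Named genes were those nearest the 10 strongest shared regions, the 3 members of each list with the highest mean fold enrichment of a shared region within 10 kb, Rxra, Rxrb and Rxrg, and the genes nearest the 10 strongest edKO peaks that were found in both edKO hearts or overlapped both WT hearts. Eci2, Hadha, Hadhb, Cpt1b, Acadl, Acadvl, Mybpc3, Dbp, Ak1, Kcnh2, Cipc, Tmem88, Tpt1, Slc39a7, Rarb, C2cd3, Cd151, Def6, Vps13d, Cldnd2 and Tpra1 fall outside this rule and were named after their values were seen, to complete short counts or to name a neighbour. Some genes that meet the rule are not reported here.

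The scripts were tested on simulated data and against bedtools. The overlaps of 4434, 4377 and 126 peaks equalled those of bedtools. Simulated peaks gave back the fragment number in 3999 of 4000 cases without scaling and in 4000 of 4000 at a scaling like that of WT replicate 4. Of 200 simulated lists of 24 genes with a share of 15%, 0 passed an unadjusted threshold of 0.05 divided by 18, and of 200 with a share of 50%, 161 did, tested against 21887 genes. Only the counts of genes with a region were drawn for these lists, with genes independent of each other. Gene positions and regions shared by neighbours were not simulated. The alternatives were −log10 q of at least 5, fold enrichment of at least 5, a reciprocal overlap of at least 50%, summits within 100 bp, each heart left out, distances of 500 or 1000 bp and 50 kb, and only the nearest gene. The computations used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.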

Results

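Retinoid X receptors (RXR) are nuclear receptors that bind DNA as obligate partners of the peroxisome proliferator-activated receptors (PPAR), liver X receptors (LXR), thyroid hormone receptors and retinoic acid receptors. RXR binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of newborn mice at postnatal day 0. The wild-type (WT) hearts were compared with hearts in which Rxra and Rxrb had been deleted in cardiomyocytes (edKO). Each genotype had 2 hearts, numbered 3 and 4, and each heart gave an RXR immunoprecipitate and an input library. Peaks had been called for each heart separately, with 19129 peaks in WT replicate 3, 4697 in WT replicate 4, 8 in edKO replicate 3 and 127 in edKO replicate 4. The sequencing depth behind these lists was recovered from the peaks' own statistics: the background of the immunoprecipitated libraries was 2.48 and 2.40 fragments per position in WT replicates 3 and 4, and 3.13 and 2.96 in edKO replicates 3 and 4. The corresponding input libraries had 2.69, 2.32, 3.11 and 3.05 fragments per position.

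The question addressed by comparing the genotypes was how much of the RXR signal depends on Rxra and Rxrb in cardiomyocytes. RXR peaks were numerous in WT hearts and few in edKO hearts: WT hearts had 11913 ± 10205 peaks (SD, n = 2) and edKO hearts 67.5 ± 84.1 (SD, n = 2), a ratio of 176. Regions at the fatty acid oxidation gene Etfb, the respiratory chain genes Cox5a and Ndufs4, the myosin light chain gene Myl4 and the nuclear receptor gene Ppard carried a peak in both WT hearts and in neither edKO heart. Of all 4342 regions with a peak in both WT hearts, 4334 had none in edKO replicate 3 and 4217 none in edKO replicate 4. The lowest WT number, 4697, lay above the highest edKO number, 127, but 2 hearts against 2 cannot give a small p-value, and the exact permutation test of the peak numbers gave a two-sided p = 0.333, the smallest this design allows. Replicates differed widely within each genotype, by 4.07 times between the WT hearts and by 15.9 times between the edKO hearts. The ratio was 69.6 without WT replicate 3, 283 without WT replicate 4, 93.8 without edKO replicate 3 and 1489 without edKO replicate 4. The recovered background was higher in each edKO immunoprecipitate than in either WT one. The value of edKO replicate 3 rests on 8 peaks, of which 25% lay at the recovered background, and no simulated list was that short. Peak lists hold no transcript or protein level, so the deletion of Rxra and Rxrb was not measured here. Among the RXR genes themselves, Rxrb had an RXR region in both WT hearts on chromosome 17 from 34031508 to 34032753 (mm10), with its summit 81 bp outside the gene, and a peak there in edKO replicate 4. The gene nearest to that edKO peak was the neighbouring zinc transporter gene Slc39a7, at 58 bp, and with only the nearest gene counted Rxrb had no region. Rxra and Rxrg had no region shared by the WT hearts within 10 kb of either gene end.

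**Figure D1:**
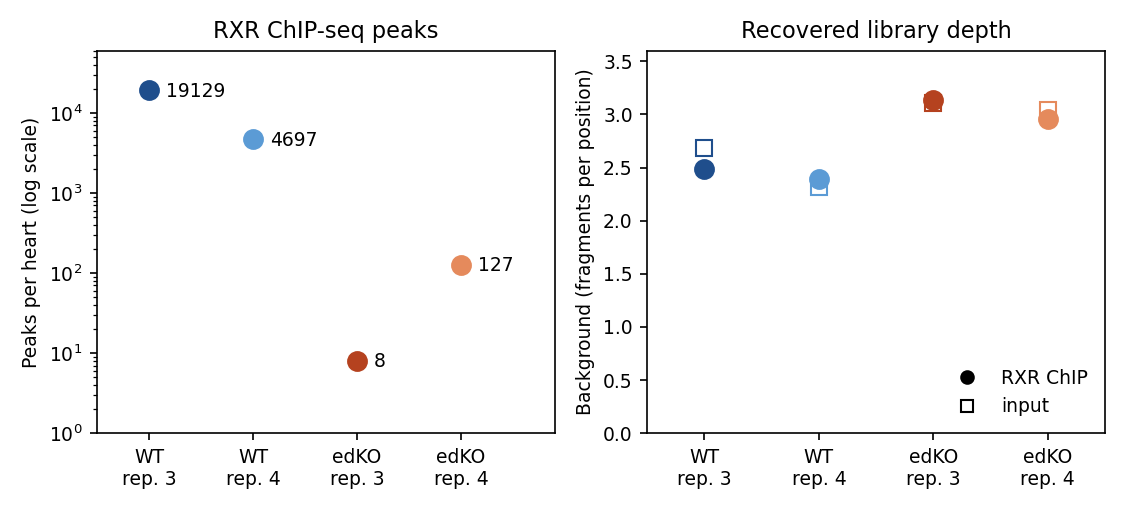
Number of RXR peaks per heart on a log scale (left) and recovered background of the RXR immunoprecipitated (filled circles) and input (open squares) libraries in fragments per position (right), 1 point per library. The WT hearts had 19129 and 4697 peaks and the edKO hearts 8 and 127, while the background of the immunoprecipitates was 2.48 and 2.40 in WT and 3.13 and 2.96 in edKO hearts.

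The WT hearts were next compared with each other to define the sites bound in both. Among the strongest shared regions were those at Myh6, the alpha myosin heavy chain gene of the adult mouse heart, near Elovl5, a fatty acid elongase gene, near Klf9, a thyroid hormone-inducible transcription factor gene, and at the channel gene Pkd2l1. These were followed by regions nearest to the transcription factor gene Klf10, the translation elongation factor gene Eef2, the cholesterol exporter gene Abca1, Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, and Wnt7b, which encodes a secreted ligand. Of the 4697 peaks of WT replicate 4, 4434 overlapped a peak of WT replicate 3 by at least 1 bp, or 94.4% (95% Clopper-Pearson interval 93.7 to 95.04%). Random placement of the same peaks within their chromosomes gave a mean of 27.2 overlaps and at most 43 in 100 draws. In the other direction, 4377 of the 19129 peaks of WT replicate 3 were shared, or 22.9% (22.3 to 23.5%). The shared peaks formed 4342 regions with 1 peak from each heart. Within the list of WT replicate 3, shared peaks had a median fold enrichment of 9.47 and the remaining 14752 peaks a median of 5.17. Within the list of WT replicate 4 the medians were 6.09 for shared peaks and 4.97 for the remaining 263. Across the 4342 regions, which are not independent replicates, the fold enrichments of the hearts had a Spearman rank correlation of 0.56.

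The fold enrichment of a peak is the authors' own value, relative to the local background of its heart. The Myh6 region, on chromosome 14 from 54966523 to 54969049 (mm10), had its summit 524 bp outside Myh6 and 2143 bp outside the neighbouring Myh7, the beta myosin heavy chain gene, with fold enrichments of 70.8 in WT replicate 3 and 51.3 in WT replicate 4. The Elovl5 region, on chromosome 9 from 77910198 to 77911495, lay 6664 bp outside the gene (64.9 and 51.02), and the Klf9 region, on chromosome 19 from 23134017 to 23136350, lay 5218 bp outside the gene (65.7 and 48.4). The Pkd2l1 region, on chromosome 19 from 44247975 to 44248750, had its summit inside the gene, 3 bp from an end (59.99 and 40.2), and was also the strongest region within 50 kb of the stearoyl-CoA desaturase gene Scd2. Klf10 had its region inside the gene (50.7 and 43.7), and the Eef2 region lay 1466 bp outside the gene (55.7 and 38.7). The region nearest to Abca1, on chromosome 4 from 53217461 to 53218986, lay 58.3 kb outside the gene (60.9 and 32.6), and that nearest to Wnt7b lay 29.0 kb outside (55.1 and 30.3). The Angptl4 region, on chromosome 17 from 33778864 to 33779951, had its summit inside the gene (64.9 and 23.6).

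Shared regions were then set against 18 gene lists to ask which kinds of genes lie near RXR sites. Genes of fatty acid oxidation, the mitochondrial pathway that supplies most of the energy of the mature heart, had the highest share: 23 of 24 had a shared region within 10 kb of either gene end, or 95.8% (95% Clopper-Pearson interval 78.9 to 99.9%). Among the other protein-coding genes the share was 15.1% (2-sided Fisher's exact test, Benjamini-Hochberg adjusted exact p = 4.96e-17, odds ratio 130). Without WT replicate 4, with all peaks of WT replicate 3 in place of shared regions, 42.4% of all genes had a peak and the odds ratio of this list fell to 31.3 (adjusted exact p = 3.44e-07). The strongest region of the list lay inside Cpt1a, which encodes the carnitine palmitoyltransferase of the outer mitochondrial membrane, on chromosome 19 from 3324718 to 3325829, with fold enrichments of 43.7 in WT replicate 3 and 39.4 in WT replicate 4. The region at Acaa2, which encodes the thiolase that ends each cycle of beta-oxidation, lay on chromosome 18 from 74778398 to 74779596 with its summit 82 bp outside the gene (41.3 and 32.7). The region at Etfb, which encodes a subunit of the electron transfer flavoprotein, lay on chromosome 7 from 43443282 to 43444318 with its summit 150 bp outside the gene and inside the neighbouring gene Cldnd2 (29.6 and 26.5). Eci2 was the member without a region. The 23 genes lay near 22 regions, since the neighbours Hadha and Hadhb, which encode the trifunctional protein, shared 1. The median fold enrichment of the 23 genes' strongest regions, averaged over both hearts, was 16.8, against 7.97 for all genes with a region, and none of 10000 random sets of 23 such genes reached it. The median was higher for LXR targets (21.9) and PPAR targets (20.8), which none of 10000 random sets of their size reached either, and for thyroid hormone (17.2) and retinoic acid targets (17.1), which 3 and 103 sets reached. Medians were lower for other lists. Lipid uptake and storage (12.7), nuclear receptors and coregulators (12.4) and sarcomere and calcium genes (11.9) were reached by 56, 29 and 31 sets. Oxidative phosphorylation (9.62) and pyruvate and the tricarboxylic acid cycle (9.35) were reached by 976 and 1735 sets. Endothelial markers, at 6.94, lay below the median of all genes with a region, and 7949 sets reached them. These sets were not matched on expression.

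Genes targeted by the lipid-sensing partners of RXR also lay near shared regions more often than other genes. Of 15 LXR targets 10 had a shared region (66.7%, interval 38.4 to 88.2%, adjusted exact p = 5.46e-05), led by the desaturase genes Scd1 (47.7 and 36.2 in WT replicates 3 and 4) and Scd2 (42.8 and 32.4) and the fatty acid synthase gene Fasn (41.8 and 28.8). Scd1 had its region on chromosome 19 from 44388376 to 44389190, 5753 bp outside the gene, and Fasn had its region on chromosome 11 from 120824019 to 120825234, with the summit inside the gene. Of 20 PPAR targets 10 had a region (50.0%, 27.2 to 72.8%, adjusted exact p = 0.000606), led by Angptl4, Cpt1a and the uncoupling protein gene Ucp3, whose region was 7109 bp outside the gene and inside the neighbouring gene C2cd3 (53.5 and 7.74). Of 24 genes of lipid uptake and storage 12 had a region (50.0%, 29.1 to 70.9%, adjusted exact p = 0.000294), led by Angptl4, the hormone-sensitive lipase gene Lipe (33.9 and 20.7) and the adipose triglyceride lipase gene Pnpla2 (19.9 and 23.0), whose region lay inside the neighbouring gene Cd151. These lists overlap: Angptl4 belonged to both the PPAR and the lipid storage list, and 4 of the 10 PPAR targets with a region also belonged to another list. Without WT replicate 4 the PPAR list no longer passed (adjusted exact p = 0.0953), and the lipid storage list rose to 22 of 24 genes (91.7%, adjusted exact p = 3.72e-06). The PPAR list also missed the threshold at a distance of 50 kb (adjusted exact p = 0.0526), and at 1000 bp the LXR (adjusted exact p = 0.226) and lipid storage lists did (adjusted exact p = 0.103), all by the same Fisher's exact test.

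**Figure D2:**
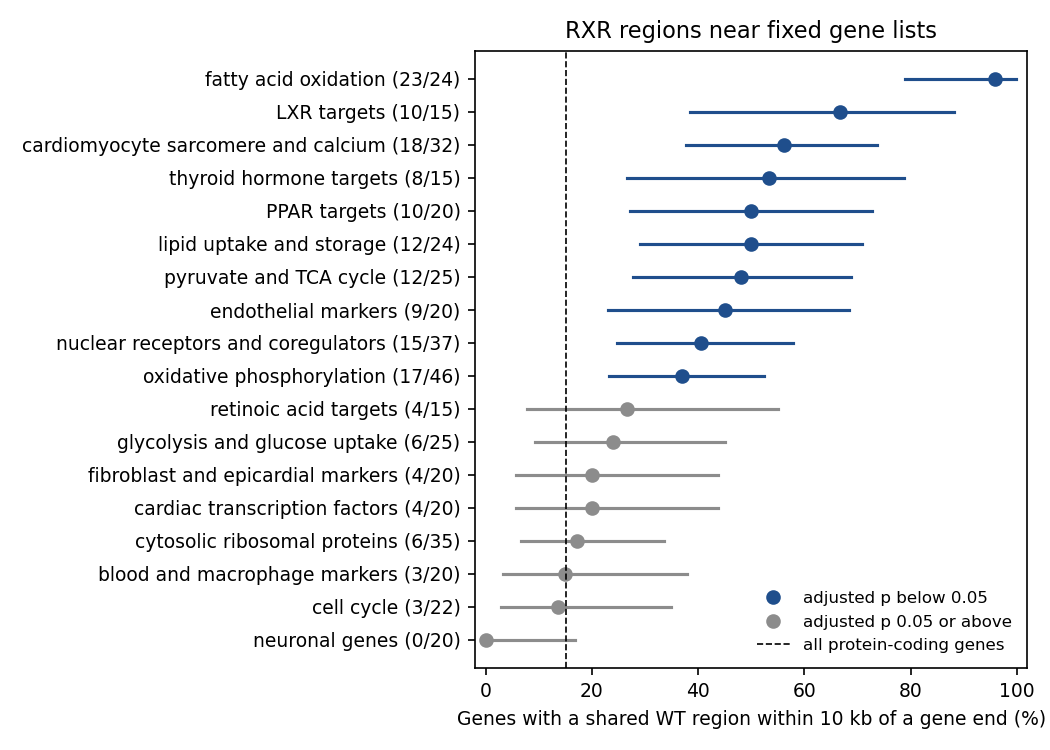
Share of the members of each gene list with a region shared by both WT hearts within 10 kb of either gene end, in percent, with the count in brackets. Points are shares, bars are 95% Clopper-Pearson intervals and the dashed line is the share of all protein-coding genes, 15.2%. Fatty acid oxidation lies highest at 95.8% and neuronal genes lowest at 0%.

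Other genes of mitochondrial energy supply lay near RXR regions more often than the remaining protein-coding genes, which were not matched on expression. Of 46 genes of oxidative phosphorylation 17 had a shared region (37.0%, 23.2 to 52.5%, adjusted exact p = 0.000606). The leading members were the cytochrome c oxidase genes Cox5a (18.3 and 15.3 in WT replicates 3 and 4) and Cox5b (17.8 and 9.92) and the complex I gene Ndufs4 (18.7 and 14.3). Of 25 genes of pyruvate oxidation and the tricarboxylic acid cycle 12 had a region (48.0%, 27.8 to 68.7%, adjusted exact p = 0.000389), led by the pyruvate dehydrogenase gene Pdhb (29.2 and 11.2), the malate dehydrogenase gene Mdh1 (23.5 and 11.2) and the isocitrate dehydrogenase gene Idh3b (12.8 and 11.0). Without WT replicate 4 the counts rose to 40 of 46 (87.0%, adjusted exact p = 1.41e-08) and 20 of 25 (adjusted exact p = 0.000580). Glycolysis and glucose uptake did not pass, with 6 of 25 genes (interval 9.36 to 45.1%, adjusted exact p = 0.370, Fisher's exact test). Its strongest members were Slc2a4, which encodes the insulin-responsive glucose transporter (24.4 and 12.6), Gapdh (21.5 and 11.7) and Gpi1 (19.6 and 5.81). The glycolysis list passed with a distance of 1000 bp (adjusted exact p = 0.0391) and of 50 kb (adjusted exact p = 0.0290). Without WT replicate 4 it rose to 16 of 25 genes (64.0%) and did not pass (adjusted exact p = 0.0670, Fisher's exact test).

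Among genes of the receptors and hormone pathways, 15 of 37 nuclear receptors and coregulators had a shared region (40.5%, 24.8 to 57.9%, adjusted exact p = 0.000501). The leading members were Nr1d2, which encodes a heme-binding repressor of the circadian clock (41.1 and 36.3), Rxrb (35.0 and 19.5) and Ppard (28.2 and 16.6), whose region lay inside the neighbouring gene Def6. With all peaks of WT replicate 3 this list rose to 27 of 37 genes (73.0%, adjusted exact p = 0.000580). Thyroid hormone targets reached 8 of 15 genes (53.3%, 26.6 to 78.7%, adjusted exact p = 0.00131), led by Myh6 and Myh7, which share 1 region, and Klf9. The thyroid list missed the threshold with all peaks of WT replicate 3 (adjusted exact p = 0.0953) and at 1000 bp (adjusted exact p = 0.226). Retinoic acid targets did not pass, with 4 of 15 genes (26.7%, 7.79 to 55.1%, adjusted exact p = 0.370). With all peaks of WT replicate 3 they reached 9 of 15 genes and did not pass either (adjusted exact p = 0.235, Fisher's exact test). The strongest members counted were the transglutaminase gene Tgm2 (24.1 and 19.2) and Dhrs3, which encodes a retinaldehyde reductase, with a region that also lay inside Vps13d (30.1 and 6.97). A stronger region, with a peak in edKO replicate 4 (6.14), lay inside the retinoic acid receptor gene Rarb (43.5 and 25.6), a member of this list, but more than 10 kb from the gene's ends, so it was not counted.

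Cardiomyocyte genes of the sarcomere and calcium handling lay near shared regions in 18 of 32 cases (56.2%, 37.7 to 73.6%, adjusted exact p = 8.47e-07, Fisher's exact test), led by Myh6, Myh7 and Myl4, the atrial and fetal myosin light chain gene (44.2 and 23.3). Cardiac transcription factor genes did not pass, with 4 of 20 (20.0%, 5.73 to 43.7%, adjusted exact p = 0.637). The strongest were Mef2d (14.9 and 9.44), Mef2a (9.47 and 6.45) and Gata6 (7.69 and 6.47). With all peaks of WT replicate 3 this list passed, at 16 of 20 genes (adjusted exact p = 0.00214). The hearts hold other cell types, and endothelial markers also passed, with 9 of 20 genes (45.0%, 23.1 to 68.5%, adjusted exact p = 0.00257), led by the nitric oxide synthase gene Nos3 (32.7 and 6.77), Eng (16.2 and 9.92) and Fli1 (11.9 and 5.33). The summits at Nos3 and Eng lay 7128 and 8531 bp from the gene, and at a distance of 1000 bp the endothelial list no longer passed (adjusted exact p = 0.877). The peaks of edKO replicate 4 in these regions were nearest to Kcnh2 and Ak1. Without WT replicate 4 the sarcomere list rose to 27 of 32 genes (84.4%, adjusted exact p = 8.03e-06) and the endothelial list to 16 of 20 (adjusted exact p = 0.00214).

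The remaining lists did not pass the threshold in the shared regions. Fibroblast and epicardial markers had a region in 4 of 20 genes (adjusted exact p = 0.637, Fisher's exact test), with Pdgfra (15.1 and 8.32), Loxl1 (8.30 and 5.84) and Vim (4.68 and 4.93) strongest. Blood and macrophage markers had 3 of 20 (adjusted exact p = 1), namely Spi1 (11.8 and 7.55), Tfrc (10.0 and 5.70) and Cd68 (6.36 and 5.55), and the Spi1 region was the same as that of the sarcomere gene Mybpc3. Cell cycle genes had 3 of 22 (adjusted exact p = 1), namely Ccnd1 (16.2 and 6.77), Cdkn1b (12.3 and 8.75) and Mcm2 (7.80 and 4.67), the last with its region inside Tpra1. Cytosolic ribosomal protein genes had 6 of 35 (17.1%, 6.56 to 33.6%, adjusted exact p = 0.724). Their strongest members were Rpl18 (51.1 and 25.8), whose region lay inside the neighbouring clock gene Dbp, Rps19 (9.47 and 7.59) and Rpl30 (9.60 and 6.54). With all peaks of WT replicate 3 the ribosomal list passed, at 24 of 35 genes (adjusted exact p = 0.00600). None of 20 neuronal genes had a region (upper limit 16.8%, adjusted exact p = 0.0988). With all peaks of WT replicate 3 the neuronal list had 5 of 20 genes, the fibroblast list 8 of 20, the blood list 6 of 20 and the cell cycle list 10 of 22. These 4 lists did not pass there either, where 42.4% of all genes had a peak.

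**Figure D3:**
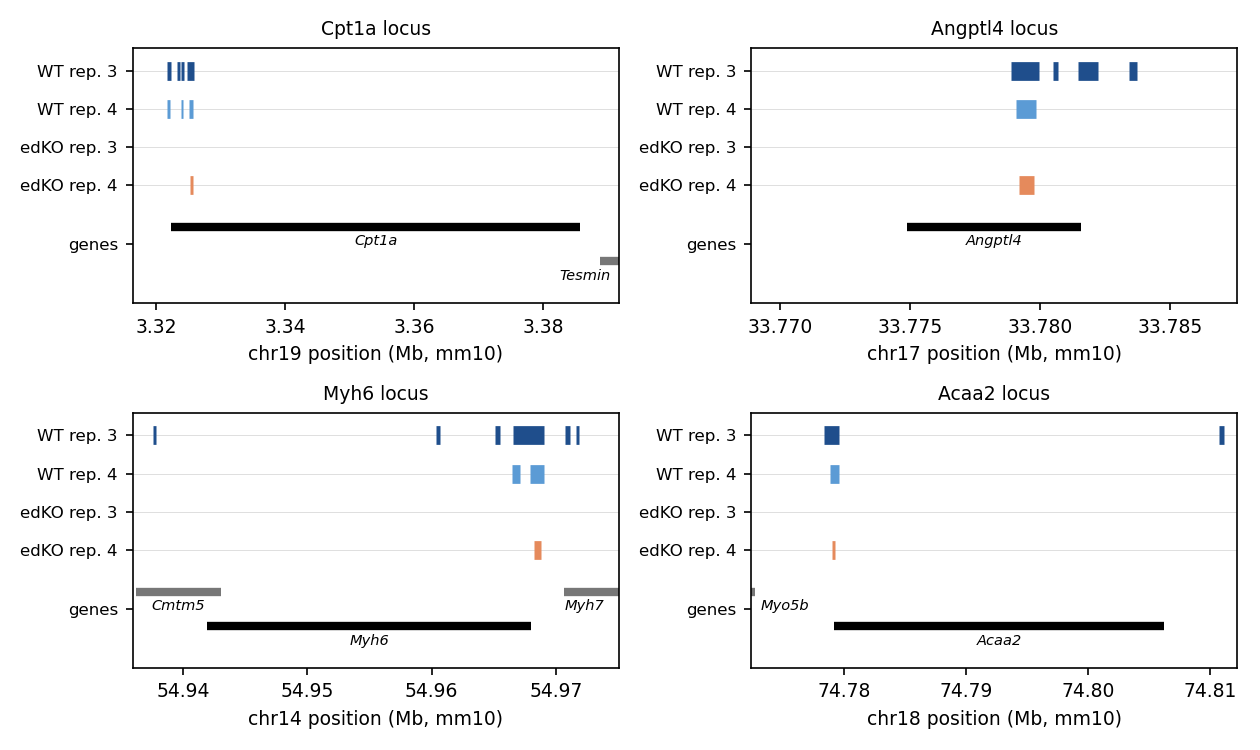
RXR peaks in each heart (coloured blocks, 1 line per heart) and genes (bars) at the Cpt1a, Angptl4, Myh6 and Acaa2 loci, with positions in Mb on mm10. At each locus both WT hearts and edKO replicate 4 had a peak in the named region, and edKO replicate 3 had none.

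The peaks left in edKO hearts were compared with the WT peaks to see whether they marked other sites. They lay at the strongest WT regions, among them those nearest to Myh6 (fold enrichment 18.7 in edKO replicate 4), Abca1 (14.4, 58.2 kb from the gene), Elovl5 (13.4), Klf9 (13.1), the phosphofructokinase-fructose-bisphosphatase gene Pfkfb3 (12.9), Klf10 (12.4) and Scd2 (11.4). The regions nearest to Ppp2r5c (11.9, 73.6 kb from the gene) and Frmd8 (11.2) were also among the 10 strongest. All 135 edKO peaks overlapped a WT peak (100%, 97.3 to 100%). In edKO replicate 4, 127 of 127 peaks overlapped WT replicate 3 and 126 overlapped WT replicate 4, where random placement gave at most 3 and 2. In edKO replicate 3, 8 of 8 peaks overlapped each WT heart (63.1 to 100%). The edKO hearts had 4 peaks in common, at Klf9, Klf10, Pkd2l1 and between Ak1 and Eng, and the other peaks of edKO replicate 3 were nearest to Fasn, Cipc, Tmem88 and Tpt1.

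Peaks in edKO replicate 4 became rarer as the WT regions became weaker. Of the 20 strongest WT regions, 20 had a peak in edKO replicate 4 (83.2 to 100%) and 3 had a peak in edKO replicate 3. Of the strongest 100, 66 and 4 had one, and of the 100 after these, 27 and 1. Of the following 300 regions, 23 (7.67%, 4.92 to 11.3%) had a peak in edKO replicate 4 and 2 in edKO replicate 3. Of the 3342 regions ranked 1001 to 4342, 3 (0.0898%, 0.0185 to 0.262%) had a peak in edKO replicate 4 and none had a peak in edKO replicate 3. Among the fatty acid oxidation genes, Cpt1a (9.10), Acaa2 (8.08), Cpt1b (6.06), Acadl (5.30) and Acadvl (3.08) had a peak in edKO replicate 4, and none had one in edKO replicate 3. No gene of the oxidative phosphorylation, tricarboxylic acid cycle or glycolysis lists had an edKO peak at its strongest shared region within 10 kb. Of all 4342 shared regions 125 (2.88%) had a peak in edKO replicate 4, and a difference between these lists was not tested. The lists also differed in WT strength, and no comparison at matched strength was made. The median fold enrichment was 16.8 for fatty acid oxidation, against 9.62 for oxidative phosphorylation, 9.35 for the tricarboxylic acid cycle and 11.6 for glycolysis. The region of Pfkfb3, a member of the glycolysis list, lay inside that gene and more than 10 kb from its ends, so it was not counted there. A peak missing from an edKO list means that the signal did not pass the authors' threshold in that heart, and a weaker signal below it was not detectable in the lists.

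**Figure D4:**
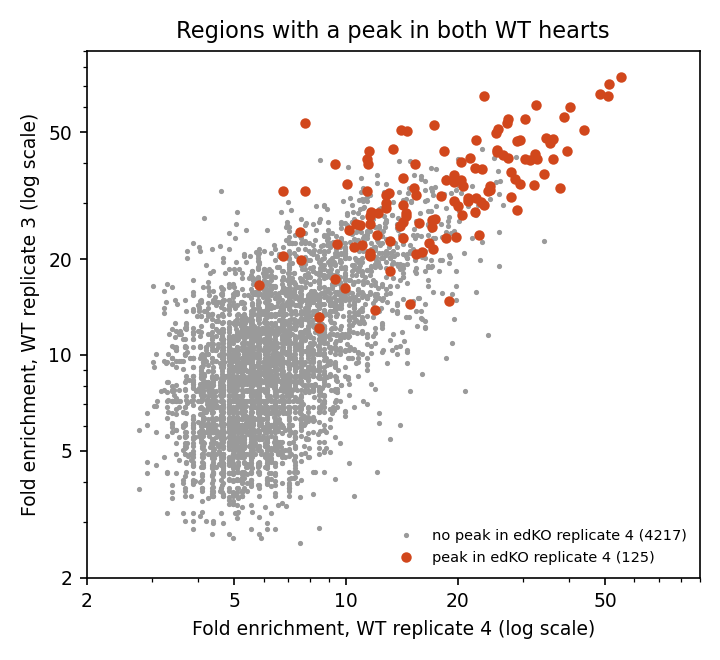
Fold enrichment in WT replicate 4 (horizontal, log scale) and WT replicate 3 (vertical, log scale) of the 4342 regions with a peak in both WT hearts, 1 point per region. The 125 regions with a peak in edKO replicate 4 (large points) lie mostly at the upper end of both lists, above most of the 4217 regions without one (small points).

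RXR regions lay close to gene ends more often than random positions did. Acaa2, Etfb, Pdhb and Rxrb were examples of genes with a region at or near an end, whereas Abca1 and Wnt7b were the nearest genes to distant regions. Abca1 also had a weaker shared region with its summit inside the gene, 1132 bp from an end (31.0 and 22.5 in WT replicates 3 and 4). That region held a peak of edKO replicate 4 (7.37). Of the 4342 shared regions, 1604 had the summit within 1000 bp of either end of a protein-coding gene, or 36.9% (35.5 to 38.4%), against a mean of 3.23% and at most 3.96% in 100 random placements. A summit inside a gene was found for 57.1%, against 41.0% at random, and a summit more than 50 kb from any gene end for 15.0%, against 48.8%. Of the 127 peaks of edKO replicate 4, 40.9% (32.3 to 50.0%) lay within 1000 bp of a gene end, as did 3 of the 8 peaks of edKO replicate 3 and 29.4% (28.7 to 30.2%) of the peaks found only in WT replicate 3. Which end of a gene is its start was not used here, so these shares cover promoters and 3' ends together.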

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

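The gene-end distances and the common −log10 p threshold were chosen after seeing the data, and the other alternatives before. The ratio of peak numbers, 176, stayed above 1 under all alternatives run. It was 155, 131 and 120 with −log10 q of at least 5, fold enrichment of at least 5 and −log10 p of at least 10, and between 69.6 and 1489 with 1 heart left out. With the replicate number as a block (WT 3 with edKO 3, WT 4 with edKO 4), the ratios within a number were 2391 and 37.0 and their geometric mean 297. The hearts share only a number, and 2 pairs allow no check of the pairing. The share of WT replicate 4 peaks in WT replicate 3, 94.4%, was 90.2% at a fold enrichment of at least 5, 70.1% with reciprocal overlap of 50% and 78.4% with summits within 100 bp. The share of edKO peaks in WT peaks fell from 100% to 35.6% with reciprocal overlap, 48 of 135, and stayed at 99.3% or above otherwise, the block included. The gene-end share, 36.9%, was 35.3% at a fold enrichment of at least 5, 34.4% with reciprocal overlap, 30.8% at 500 bp, and 31.2 to 36.8% with 1 WT heart left out. The cause of these shifts was not tested, but reciprocal overlap of 50% by construction excludes narrow peaks inside wide ones. Of the alternative values of the gene lists other than fatty acid oxidation, 142 stayed on their side of the threshold, 7 no longer passed and 4 newly passed, and none of the lists that passed turned direction. Genes with a region numbered 3318, against 9286 with all peaks of WT replicate 3, 1835 at 1000 bp and 6988 at 50 kb. Of the named genes' values 414 stayed and 10 moved where the gene kept a region. Named genes left without a region numbered 29 at 1000 bp (among them Angptl4, Scd1 and Klf9), 10 with reciprocal overlap (among them Myh6, Abca1 and Gapdh), 7 with only the nearest gene (among them Rxrb, Ppard and Myh7), 3 with summits within 100 bp (Klf9, Spi1 and Rps19) and 2 each at the stricter q and fold enrichment (Vim and Mcm2). The motif test and its alternatives were not run. The weakest called summit held 11 and 12 fragments in WT replicates 3 and 4, and 24 and 17 in edKO replicates 3 and 4, so weaker signals lie below these lists.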

Other observations

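The 5 gene lists of the next paragraphs were added after seeing the data, and those of desaturation and elongation and of the circadian clock were made because members had been seen near strong regions, so their tests are not independent. The members named there were chosen after their values were seen. The tests of a common −log10 p threshold, of a uniform remainder, against either WT heart, and of carried-over material were also chosen after the results were seen, the last when its value was known.

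Genes that desaturate and elongate fatty acids had a shared WT region in 8 of 18 cases (44.4%, adjusted exact p = 0.00725, 2-sided Fisher's exact test, adjusted over the 5 added lists). Elovl5 (64.9 and 51.02 in WT replicates 3 and 4), an elongase gene of polyunsaturated fatty acids, and Scd1, a desaturase gene of monounsaturated fatty acid synthesis, led the list. Fads1 (11.5 and 8.75) and Fads2 (15.8 and 6.13), desaturase genes of polyunsaturated fatty acid synthesis, each had a region. With all peaks of WT replicate 3 in place of shared regions this list no longer passed (adjusted exact p = 0.0672), and over the alternatives the adjusted p ran from 0.000785 to 0.235. Circadian clock genes had a region in 14 of 24 cases (58.3%, adjusted exact p = 7.13e-06, alternatives 7.17e-07 to 0.0762), led by Dbp (51.1 and 25.8), Nr1d2 (41.1 and 36.3) and Tef (32.1 and 18.4). Per1, Per2 and Per3 each had one, with 10.6 and 7.55 at Per1.

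Peroxisomal genes had a region in 9 of 28 cases (32.1%, adjusted exact p = 0.0360, Fisher's exact test, alternatives 0.00280 to 0.859), with Pex2 (31.9 and 17.2) and Acaa1a (21.2 and 17.2) strongest. Genes of coenzyme A synthesis, mitochondrial import and mitochondrial DNA upkeep had 8 of 23 (34.8%, adjusted exact p = 0.0268, alternatives 0.00384 to 0.0373), with the mitochondrial coenzyme A carrier gene Slc25a42 (19.4 and 5.84) strongest and the chaperonin genes Hspd1 and Hspe1 sharing 1 region. Genes of branched-chain amino acid breakdown, another fuel of the mitochondrion, had 2 of 22, Bckdha and Hibch (9.09%, 1.12 to 29.2%, adjusted exact p = 0.563, alternatives 0.504 to 1). With all peaks of WT replicate 3 the peroxisomal list had 19 genes (67.9%), the coenzyme A and import list 18 (78.3%) and the branched-chain list 9 (40.9%). Of all genes, 42.4% had a peak there. The difference between the branched-chain list and the others was not tested.

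The recovered background of the WT immunoprecipitates was 2.48 and 2.40 fragments per position and that of their inputs 2.69 and 2.32, while the peak numbers differed by 4.07 times. With the summits and local backgrounds of WT replicate 3 scaled to 96.5%, the immunoprecipitate level of WT replicate 4, and the difference between the inputs left out, 18720 of the 19129 peaks of WT replicate 3 still passed the smallest −log10 p of WT replicate 4, 4.70.

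The small number of peaks in edKO hearts was not matched by lower depth: the lowest recovered background of an edKO immunoprecipitate was 1.23 times that of WT replicate 4. For edKO replicate 3 the recovered background rests on 8 peaks only. A stricter p behind the same q in the shorter lists does not account for it either, since the ratio of peak numbers was 120 at a common −log10 p of at least 10. A lower yield of the immunoprecipitation in both edKO hearts stays open, because 0 edKO peaks lay outside the WT peaks and no site in these lists is known to be independent of RXR. The loss of Rxra and Rxrb in cardiomyocytes named by the design is the candidate biological explanation, and it cannot be told apart from a lower yield here.

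Whether the peaks left in edKO replicate 4 are a uniform remainder of the WT signal stays open. Over the 20 strongest shared regions the fragments at the peak summits did not depart from 1 ratio to those of WT replicate 3 beyond counting error (chi-square p = 0.892). The excess over background ran from 13.4% (Wnt7b) to 23.2% (Myh6) of that in WT replicate 3, with a median of 17.9%. The strongest peak of edKO replicate 4 in a region was used, and its summit can lie elsewhere than in WT replicate 3. At Klf9 it lay 6272 bp from the gene, against 5218 bp in WT replicate 3. An edKO peak nearer that summit, at 5183 bp, had a fold enrichment of 7.47, against 13.1. Against WT replicate 4 counting error also allowed 1 ratio (chi-square p = 0.214), but the excess ran from 17.9% (Nr1d2) to 42.9% (Angptl4) with a median of 23.96%, and the WT hearts did not keep 1 ratio to each other (chi-square p = 3.60e-05). The highest excess was 2.40 times the lowest against WT replicate 4, and 2.48 times between the WT hearts. With only 33 to 76 fragments per region in edKO replicate 4, the test can thus miss a spread of this size. Cardiomyocytes in which the deletion was incomplete could give such a remainder, but so could WT chromatin or reads carried into the library of edKO replicate 4, for which the same test decides nothing, or a lower yield. The design names only Rxra and Rxrb as deleted, so other sources are not excluded. Sites bound in cells other than cardiomyocytes were tested by the share of genes with an edKO peak. This was 3 of 18 sarcomere and calcium genes against 2 of 16 endothelial, fibroblast and blood genes (Fisher's exact p = 1). Myh6 and Myh7 share 1 region, and the peaks counted for Nos3 and Eng were nearer to Kcnh2 (5994 bp) and Ak1 (3017 bp). These counts are too small to decide, and the peaks cannot be assigned to a cell type.

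Open promoters of abundantly used genes were weighed as an explanation for the nearness of RXR regions to fatty acid oxidation genes. Of the fatty acid oxidation genes 23 of 24 had a shared region, against 6 of 35 cytosolic ribosomal protein genes (2-sided Fisher's exact p = 6.92e-10). Over the alternatives this p ran from 2.63e-10 to 0.0185, the latter with all peaks of WT replicate 3, where 24 of 35 ribosomal genes had a peak. Ribosomal protein genes thus did not reach the share of fatty acid oxidation genes, but they are 1 comparison set. Expression and open chromatin were not analysed here, so the explanation is not excluded. Binding of RXR to this pathway stays a hypothesis.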
